A study of Mus musculus with 24 samples.

How the data were processed

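The data are counts of polyA RNA reads per gene in 24 libraries of mouse cervical spinal cord, made with an unstranded TruSeq v2 protocol. The labels describe each group as separate animals, so a replicate is taken as an animal. Xist, the transcript of the inactive X chromosome, was at most 0.196 CPM in every library, and Y-linked genes were expressed in all. Xist had at most 6 reads in a library and 0 in every Tg-90d library. A fit with Xist as a covariate rests on these few reads and does not measure an effect of sex. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned to GRCm38 with STAR 2.5.2 and counted with HTSeq 0.9.1. The deposited unit is the count of reads per gene, as whole numbers, and the lines for reads without a feature or with an ambiguous gene were taken out of the counts and used as library measures. The no-feature share, the percent of reads outside genes, had group means ± SD of 5.29 ± 0.147 (nTg-60d), 4.78 ± 1.03 (nTg-120d), 5.53 ± 0.289 (Tg-60d), 3.95 ± 0.654 (Tg-90d) and 5.20 ± 1.01 (Tg-120d).

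Depth ran from 23.0 M (Tg-60d replicate 3) to 37.4 M counts (nTg-120d replicate 5), with group means of 33.7, 34.0, 27.7, 32.6 and 30.3 M in nTg-60d, nTg-120d, Tg-60d, Tg-90d and Tg-120d. Replicates of a group differed by 4.34 to 76.4 times the variance of counting alone over 46 pairs. The files hold 52636 genes, and 18791 passed the edgeR expression filter. Coordinates came from GENCODE M21, which held 18219 of the tested symbols.

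Groups came from the labels, and tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Counts were scaled by TMM and fitted with edgeR 4.0.16 (robust quasi-likelihood, a mean for each group, all 24 libraries) in R 4.3.3, and p values were adjusted by Benjamini-Hochberg over all tested genes, with calls under 0.05. Standard errors are the absolute log2 fold change over the square root of the F statistic. The 8 comparisons were Tg against nTg at 60 and at 120 days, Tg at 90 against 60, 120 against 90 and 120 against 60 days, nTg at 120 against 60 days, Tg at 90 days against the mean of both nTg groups, and the interaction of genotype with age. Lists of genes (34, each with at least 5 tested members) were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison, with fry and an estimated correlation as alternatives. CPM values use library totals scaled by TMM.

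Named genes followed a rule. Fus and Thy1 came first, then up to 12 highest and 12 lowest log2 fold changes among called genes of at least 1 CPM, then up to 4 called members with the lowest p in each list. Chat, Gfap, Aif1 and Mbp were always named, and up to 10 genes called in both of 2 comparisons set side by side were added. Predicted genes and pseudogenes may go unnamed.

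Alternatives were DESeq2 1.42.0, limma voom 3.58.1, other filters and scalings, only the groups compared, a replicate block, a term read from the file numbers, a covariate for Xist, thinned counts, a fold limit, and fits without each library. Fits added after the libraries had been seen had the no-feature share as a covariate, or left out the libraries with a share under 4%, or Tg-120d replicates 1 and 3.

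The tests were tried on simulated data drawn from a negative binomial with the fitted mean and dispersion of each gene, in which 200 genes were changed by log2 values of 0.5, 1 or 2. For Tg against nTg at 60 days (18465 genes tested) 38.5%, 72.3% and 100% of these changes were called and 5.23% of calls were false, and at 120 days (18475) 36.9%, 68.7% and 92.2%, with 3.55% false. For Tg at 90 against 60 days (18461) they were 39.4%, 65.2% and 90.9%, with 4.83% false, at 120 against 90 days (18499) 28.8%, 60% and 95.5%, with 3.03% false, and at 120 against 60 days (18454) 41.5%, 76.9% and 92.4%, with 8.81% false. For nTg at 120 against 60 days (18470) they were 44.6%, 76.9% and 95.3%, with 4.58% false, for Tg at 90 days against the mean of nTg (18477) 41.5%, 82.1% and 92.2%, with 5.1% false, and for the interaction (18446) 13.4%, 54.5% and 82.8%, with 5.61% false. A simulated list of 20 genes shifted by 0.5 had a camera p of 7.94e-30 for Tg against nTg at 60 days, and an unshifted list had 0.674. For Tg against nTg at 120 days they had 7.88e-32 and 0.0184, so the unshifted list fell below 0.05 there. Unshifted lists had a camera p of 0.243 to 0.787 in the remaining comparisons. Simulated genes were drawn independently of each other, so these lists do not test the preset correlation.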

Results

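The series holds 24 polyA RNA libraries of mouse cervical spinal cord from transgenic animals (Tg) that carry truncated human FUS and from non-transgenic animals (nTg). The groups are nTg at 60 days (5 libraries), nTg at 120 days (5), Tg at 60 days (5), Tg at 90 days (4) and Tg at 120 days (5), and there is no nTg group at 90 days. The labels give the youngest control group an age of 30 to 60 days. In comparisons with these controls, interaction included, a younger age cannot be told apart from the effect tested. A gene was called when its Benjamini-Hochberg adjusted p from edgeR quasi-likelihood tests was under 0.05, and changes are given as log2 fold change ± standard error. Of 52636 genes in the deposited files, 18791 were tested. Lists of genes fixed beforehand were tested with camera. Each list call lost under a correlation estimated from the data carries that adjusted p beside it, and the other list calls were kept. Members of a list are given as higher, lower and not passing, in this order.

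Counts on mouse Fus, an RNA-binding protein of the FET family linked to ALS, were higher in every Tg than in every nTg library. Mean Fus was 141 and 147 CPM in nTg at 60 and 120 days, and 325, 401 and 239 CPM in Tg at 60, 90 and 120 days. Single libraries ran from 101.1 to 168 CPM in nTg and from 200.5 to 433 CPM in Tg. Thy1, a neuronal surface glycoprotein whose promoter is widely used in transgenes, had means of 536 and 673 CPM in nTg and 1410, 1921 and 793 CPM in Tg at 60, 90 and 120 days. Mouse Fus lies on chromosome 7 (127967457 to 127985701, GRCm38, plus strand) and Thy1 on chromosome 9 (44043384 to 44048579, plus strand).

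**Figure D1:**
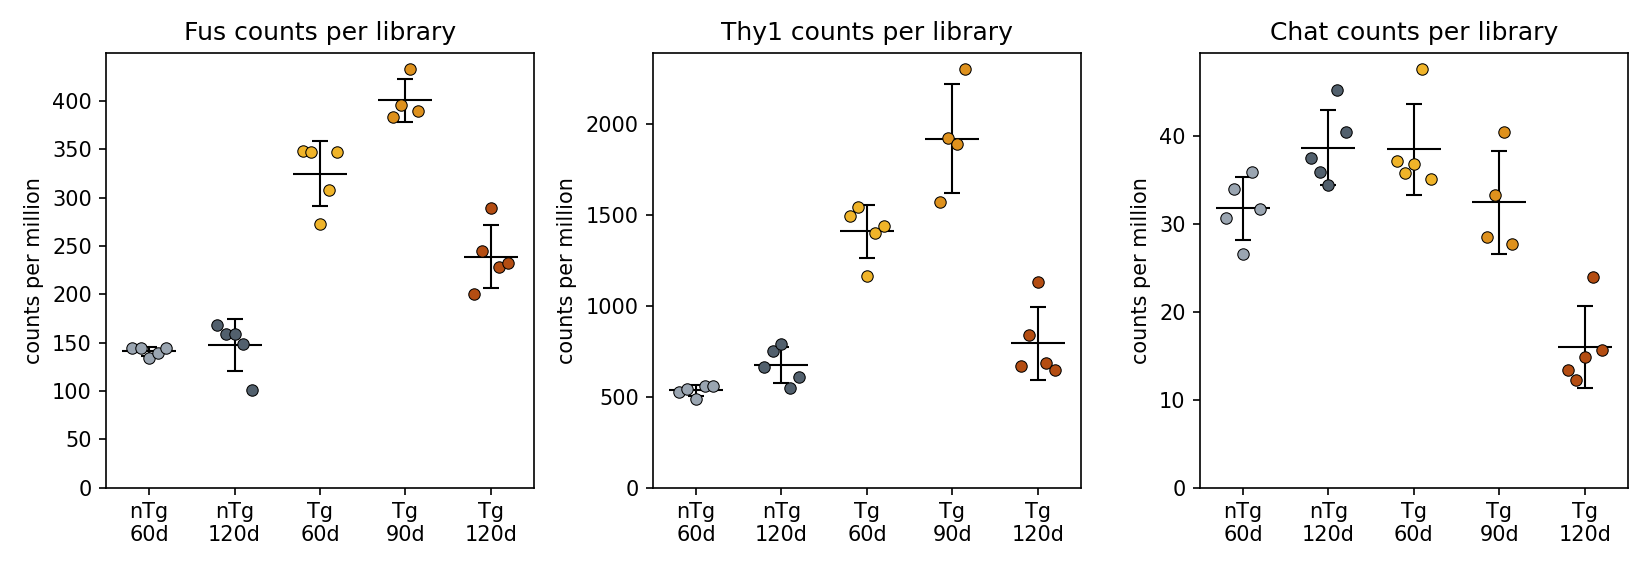
CPM of Fus, Thy1 and Chat in each library by group. Mean Chat was 31.8 and 38.7 CPM in nTg at 60 and 120 days and 38.5, 32.5 and 16.1 CPM in Tg at 60, 90 and 120 days.

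Pseudogenes that share sequence with Fus had low counts in nTg and higher in Tg, and the means of Gm10167 and Gm7199 were highest at 90 days, as for Fus. Gm10167, a processed pseudogene on chromosome 5 (148182899 to 148184377, minus strand), shares 45.6% of its 25-base words with Fus and had means of 2.51 and 3.06 CPM in nTg against 149, 174.5 and 50.8 CPM in Tg at 60, 90 and 120 days. Gm7199, a processed pseudogene on chromosome X (163477652 to 163479136, plus strand), shares 12.1% and had 0.0114 and 0.00677 CPM in nTg against 15.6, 24.1 and 6.55 CPM in Tg. Gm8309, on chromosome 7 (95461991 to 95463438), shares 8.29%, with means of 0.806, 0.425 and 0.238 CPM in Tg at 60, 90 and 120 days. Above the mean of nTg, the excess of Fus was 183.5, 256 and 91.8 CPM at 60, 90 and 120 days, and that of Thy1 was 874, 1316 and 120 CPM. The excess at 120 days was 0.358 of that at 90 days for Fus, 0.0912 for Thy1, 0.278 for Gm10167 and 0.272 for Gm7199. The human FUS sequence is not in the mouse reference, so these counts measure only reads that aligned to mouse sequence.

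At 60 days few genes differed between Tg and nTg spinal cord. Fus, Thy1 and the pseudogenes Gm10167, Gm7199 and Gm8309 had the lowest adjusted p values, and no member of the motor neuron, glial or immune lists passed. As lists, cholesterol synthesis, interferon-stimulated and myelin genes were called lower and skeletal muscle genes higher (each adjusted p = 0.589 with an estimated correlation), with no member called over all genes. Of 18791 genes, 26 were called, 21 higher and 5 lower, 23 of them with an absolute log2 fold change of at least 1, while 1554 had an unadjusted p below 0.05. DESeq2 called 74 genes, limma voom 47, a filter at a mean of 1 CPM 9, thinned counts 15 and a term read from the file numbers 15.

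Fus rose by 1.20 ± 0.109 (adjusted p = 4.25e-07) and Thy1 by 1.40 ± 0.135 (9.03e-07) at 60 days. Gm7199 rose by 9.94 ± 0.487 (1.30e-12), Gm10167 by 5.89 ± 0.232 (2.61e-14) and Gm8309 by 5.23 ± 0.507 (9.03e-07). Among other called genes, Cap2, an actin-regulating cyclase-associated protein on chromosome 13 (46501848 to 46650281), rose by 0.48 ± 0.0784 (0.0051). Fam92a, a membrane-shaping protein of cilia that shares 0.73% of its words with Fus, rose by 0.30 ± 0.0626 (0.0486). Lower in Tg were Glra4, a glycine receptor subunit on chromosome X (136757674 to 136780141), by −1.81 ± 0.34 (0.0223). Nes, an intermediate filament of progenitors and reactive astrocytes on chromosome 3 (87971078 to 87980451), fell by −0.60 ± 0.116 (0.0272). Other called genes were Rpl10-ps3 (2.90), Gm2000 (2.23), Srp54a (−1.40) and the processed pseudogenes Glud-ps (1.41) and Gstp-ps (1.17). Chat, the acetylcholine-synthesizing enzyme of motor neurons, did not pass (0.28, 0.649), nor did the astrocyte filament Gfap (−0.13, 0.925), the microglial marker Aif1 (−0.17, 0.921) or the myelin protein Mbp (−0.37, 0.505).

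Cholesterol synthesis genes, the sterol pathway enzymes active in myelinating cells, were called lower as a list at 60 days (camera adjusted p = 8.98e-14, adjusted p = 0.589 with an estimated correlation), with a median of −0.50. None of 25 members was called over all genes, and 15 were lower when adjusted over the list alone. In nTg-60d replicate 4 the sterol enzyme gene Hmgcs1, looked at after its values were seen, was at 266 CPM, against 656 to 1190 CPM in the other nTg-60d libraries. Interferon-stimulated genes were lower as a list (median −0.45, 3.76e-08, adjusted p = 0.589 with an estimated correlation). Lower too were myelin and oligodendrocyte genes (median −0.36, 1.3e-06) and genes of meninges and fibroblasts (median −0.39, 0.00056). So were endothelial and pericyte (0.00286), autophagy and lysosome (0.00297) and oligodendrocyte precursor genes (0.00918). With an estimated correlation these last lists had adjusted p = 0.589, 0.664, 0.589, 0.664 and 0.589 in this order. Disease-associated microglia genes sat at the boundary (lower, 0.0486, adjusted p = 0.664 with an estimated correlation). For it, 10 of the 24 fits without a single library ended the call, with values up to 0.239, as did the file-number term (0.142) and the share of reads without a feature as a covariate (0.153), which also ended that of lysosome genes (0.0522). Skeletal muscle genes were higher (median 1.82, 3.84e-06, adjusted p = 0.589 with an estimated correlation). Higher too were glucocorticoid response genes (median 0.25, 0.00983, adjusted p = 0.671 with an estimated correlation). No member of these lists was called over all genes. Motor neuron genes were not called as a list (0.0722), although 6 fits without a single library called them (to 0.0215). FET family and ALS-linked genes, of which only Fus passed, had a median of −0.0009 and a mean of 0.028 with the test pointing lower (0.932).

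The count of 26 called genes at 60 days was 289 without nTg-60d replicate 4, 17, 16, 13 and 17 without nTg-60d replicates 1, 2, 3 and 5, and 13, 12, 15 and 13 without Tg-60d replicates 1, 2, 3 and 4. Single libraries also ended the list calls of oligodendrocyte precursors (0.058 without nTg-60d replicate 5), meninges (0.0632 without Tg-60d replicate 1) and glucocorticoid response (0.239 without Tg-60d replicate 4), and the calls of Glud-ps (0.0516 without nTg-60d replicate 3), Nes (up to 0.128 without nTg-60d replicate 5 or Tg-60d replicate 1, 3 or 4) and Fam92a (up to 0.223, in 17 fits).

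At 90 days the means of Fus, Thy1, Gm10167 and Gm7199 were at their highest, although the step of Fus from 60 days did not pass (0.30, 0.0602). Few other genes differed from the mean of the nTg groups at 60 and 120 days. As lists, ribosomal protein and oxidative phosphorylation genes were called higher and excitatory and inhibitory transmission genes lower (each adjusted p = 0.76 with an estimated correlation). Neither motor neuron nor astrocyte genes were called as lists. Against this mean 33 genes were called, 21 higher and 12 lower, and 4683 had an unadjusted p below 0.05. There is no nTg group at 90 days, so age and genotype cannot be separated here. A total of 3332 genes (1749 higher, 1583 lower) were called against nTg at 60 days alone and 12 (9 higher, 3 lower) against nTg at 120 days alone.

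Fus rose by 1.47 ± 0.0955 (adjusted p = 3.01e-10) and Thy1 by 1.68 ± 0.117 (1.18e-09) at 90 days, with Gm7199 at 10.91 and Gm10167 at 5.98. Higher too were Rnaset2a, a lysosomal ribonuclease on chromosome 17 (8115445 to 8148097) (1.10, 0.00569), the proteasome subunit Psma3 (0.62, 0.00569), the iron regulator Hfe (0.65, 0.0428) and the ribosomal protein Rpl5 (0.42, 0.0482). Lower were Gm3608, a pseudogene on chromosome 1 (105455971 to 105458829) (−5.25, 2.24e-09) and the matrix peroxidase Pxdn on chromosome 12 (29937608 to 30017658) (−1.29 ± 0.186, 0.000764). Lower by less were the oligodendrocyte lineage transcription factor Myt1 (−0.77, 0.000744), the intracellular calcium channel Itpr2 (−0.64, 0.00115) and the Ras regulator Nf1 (−0.45, 0.00569). Chat (−0.11, 0.633), Gfap (0.18, 0.41), Aif1 (0.31, 0.223) and Mbp (0.05, 0.868) did not pass.

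Ribosomal protein genes, which code for the translation machinery, were called higher as a list at 90 days (median 0.38, camera adjusted p = 4.44e-19, adjusted p = 0.76 with an estimated correlation). Of 32 members 1 was called over all genes and 32 when adjusted over the list alone. Oxidative phosphorylation genes were higher (median 0.24, 6.02e-09), with 0 of 27 called over all genes and 20 adjusted over the list alone. Disease-associated microglia genes (0.00196; 8 adjusted over the list alone), immediate early genes (0.002; 3), autophagy and lysosome genes (0.00436), integrated stress response genes (0.0111) and neuronal injury genes (0.0424; 2) were higher too. Excitatory transmission genes (0.00356; 7 lower adjusted over the list alone), interferon-stimulated genes (0.0111) and inhibitory transmission genes (0.0321; 5 lower) were lower. Every one of these calls had an adjusted p = 0.76 with an estimated correlation. Homeostatic microglia genes were not called (0.0507), although 13 fits without a single library called them.

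The count of 33 was 1272 with DESeq2, 52 with voom, 16 with only the groups compared, 19 with the file-number term, 13 with an Xist covariate, 18 with the share of reads without a feature as a covariate and 9 without the libraries with a share under 4%. It was 18, 20 and 56 without nTg-60d replicates 2, 3 and 4, 383 and 997 without nTg-120d replicates 2 and 3, 13, 1732 and 10 without Tg-90d replicates 2, 3 and 4, and 51 without Tg-120d replicate 3. Calls ended for Rnaset2a (0.077 at most) and Nf1 (0.0684) without Tg-90d replicate 2 or 4, for Psma3 (0.0867) without Tg-90d replicate 4, for Rpl5 in 17 fits (to 0.418) and for Hfe in 13 (to 0.32), and among lists for interferon-stimulated genes (0.0538 without Tg-90d replicate 3), inhibitory transmission (0.342 without Tg-90d replicate 4) and neuronal injury (to 0.0934 without nTg-120d replicate 3 or Tg-90d replicate 1 or 2). The covariate ended the list calls of interferon-stimulated (0.715), neuronal injury (0.519), integrated stress response (0.0968), lysosome (0.9) and oxidative phosphorylation genes (0.0968), and the fit without the libraries with a low share those of inhibitory transmission (0.0516), neuronal injury (0.106) and integrated stress response genes (0.114).

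At 120 days motor neuron genes were lower as a list in Tg than in nTg, and disease-associated microglia, complement, inflammatory and reactive astrocyte genes were higher. Other lists were called with a call lost under an estimated correlation, namely interferon-stimulated (higher, adjusted p = 0.161 with an estimated correlation), pan-neuronal (lower, 0.0746), cholesterol synthesis (lower, 0.342), glucocorticoid response (higher, 0.263), immediate early (higher, 0.352) and cell cycle genes (higher, 0.589). Mean Fus, Gm10167 and Gm7199 were above nTg by fewer CPM than at the younger ages. Against nTg at 120 days 7479 genes were called, 4008 higher and 3471 lower, with 1695 of them at an absolute log2 fold change of at least 1 and 8908 genes at an unadjusted p below 0.05.

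Fus rose by 0.70 ± 0.108 at 120 days (adjusted p = 1.41e-05), and Thy1 did not pass (0.24 ± 0.133, 0.164). Motor neuron genes fell as a list (camera adjusted p = 4.7e-10, adjusted p = 0.0352 with an estimated correlation), with 1 member higher, 17 lower and 1 not passing. Chodl, a lectin of fast motor neurons on chromosome 16 (78930948 to 78951733), fell by −4.59 ± 0.176 (3.10e-15), from 56.8 CPM in nTg to 2.33 CPM in Tg. The motor neuron transcription factors Isl2 (−2.51, chromosome 9, 55538672 to 55546180) and Mnx1 (−2.08) fell. Mmp9, a protease of vulnerable motor neurons, fell (−1.64), as did Chat on chromosome 14 (32408203 to 32465989) (−1.27 ± 0.146, 2.14e-07). Pan-neuronal and neurofilament genes fell as a list (2 higher, 16 lower, 1 not passing; 3.42e-08, adjusted p = 0.0746 with an estimated correlation). The heavy, medium and light neurofilament genes Nefh (−2.004 ± 0.121), Nefm (−1.71) and Nefl (−1.28) led it with Vamp1, a vesicle protein of fast-firing synapses (−0.90). Nefh on chromosome 11 (4938754 to 4948064) went from 1830 CPM in nTg to 456 CPM in Tg. Inhibitory (5 higher, 7 lower, 4 not passing; 0.429) and excitatory transmission genes (3, 6 and 9; 0.526, median −0.02 and mean 0.04) were not called as lists.

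Disease-associated microglia genes, the phagocytic state seen around damaged neurons, rose as a list at 120 days (19 higher, 0 lower, 3 not passing, 20 higher adjusted over the list alone; 2.5e-18, adjusted p = 0.00361 with an estimated correlation). The integrin Itgax on chromosome 7 (128129547 to 128150657) rose by 4.93 ± 0.209 (2.04e-14), from 1.09 to 33.3 CPM, with the glycoprotein Gpnmb (4.29 ± 0.247), the lysosomal marker Cd68 (2.82 ± 0.149) and the receptor kinase Axl (1.41). Homeostatic microglia genes rose too (11 higher, 1 lower, 2 not passing; 2.36e-05, adjusted p = 0.263 with an estimated correlation), among them the hexosaminidase Hexb (1.43 ± 0.11) and the growth factor receptor Csf1r (1.23). Aif1 rose by 1.22 ± 0.173 (3.97e-06). Complement and antigen presentation genes rose (17, 1 and 3; 1.72e-11, adjusted p = 0.0217 with an estimated correlation), as in the complement starters C1qa (2.51 ± 0.167) and C1qc (2.36), the class I light chain B2m (1.88) and the protease Ctss (2.00). All 24 interferon-stimulated genes rose (1.02e-13, adjusted p = 0.161 with an estimated correlation). Cxcl10, a T cell attractant, stood at 3.96 ± 0.451, the deubiquitinase-like Usp18 at 2.77, Trim30a at 2.18 and the transcription factor Irf9 at 1.47. Inflammatory cytokine genes rose (19, 0 and 2, camera 1.77e-10, adjusted p = 0.000531 with an estimated correlation), such as the pattern receptor Tlr2 (2.36 ± 0.149) and the chemokine Cxcl16 (1.76). The largest rises outside pseudogenes included the protease inhibitor Cst7 (5.70), the lectins Cd22 (5.26) and Clec7a (4.52), the antiviral GTPase Mx1 (4.48) and the endolysosomal protease Ctse (4.40). Lymphocyte genes (0 of 6 called; 0.893) and infiltrating myeloid genes (6, 0 and 10; 0.078) were not called as lists, although the lysozyme gene Lyz2 (2.67) and the macrophage gene Ms4a7 (2.87) rose.

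Reactive astrocyte genes rose as a list (18 higher, 0 lower, 2 not passing; 1.28e-16, adjusted p = 0.000531 with an estimated correlation). Serpina3n, a secreted protease inhibitor on chromosome 12 (104406729 to 104414329), rose by 3.01 ± 0.108 (1.07e-15), the filament Vim by 3.15, the surface protein Cd109 by 4.37 and the metalloprotease inhibitor Timp1 by 3.98. Gfap on chromosome 11 (102887336 to 102900912) rose by 2.34 ± 0.15 (1.57e-11), from 2005 CPM in nTg to 10150 CPM in Tg. General astrocyte markers rose (11, 0 and 3; 6.15e-05, adjusted p = 0.114 with an estimated correlation), including the folate enzyme Aldh1l1 (1.17) and the water channel Aqp4 (1.49). Oligodendrocyte precursor genes rose (7, 0 and 5, camera 0.00197, adjusted p = 0.263 with an estimated correlation), with the growth factor receptor Pdgfra at 0.83 and the proteoglycan Vcan at 1.31. Myelin genes were not called as a list (3, 6 and 12; 0.139), Mbp on chromosome 18 (82475146 to 82585637) did not pass (−0.16, 0.426), and the connexin Gjc2 fell by −1.45. Cholesterol synthesis genes fell (0, 21 and 4; 7.65e-09, adjusted p = 0.342 with an estimated correlation), as in the desmosterol reductase Dhcr24 (−1.42) and the LDL receptor Ldlr (−1.09).

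Stress lists split at 120 days. Glucocorticoid response genes rose (13 higher, 0 lower, 2 not passing; 8.15e-07, adjusted p = 0.263 with an estimated correlation), with the metallothioneins Mt1 (2.59) and Mt2 (2.61) and the receptor chaperone Fkbp5 (1.65). Neuronal injury genes (8, 0 and 9, camera 0.00484, adjusted p = 0.198 with an estimated correlation) were called higher as a list, led by the transcription factors Atf3 (2.32 ± 0.339) and Jun (0.82). Immediate early genes rose (12, 1 and 4; 0.000659, adjusted p = 0.352 with an estimated correlation). The matrix protein gene Cyr61 stood at 4.80, the zinc finger gene Egr2 at 2.85 and Junb at 1.73, while the synaptic gene Arc fell by −1.29. Tg-120d replicate 3, a library with caudal Hox transcripts, stood apart for this list (mean 4.65 log2 CPM, next 3.65). Cell cycle genes rose (15, 0 and 4; 0.00106, adjusted p = 0.589 with an estimated correlation), as in the topoisomerase Top2a (2.86) and the reductase Rrm2 (1.76). Ribosomal protein genes were called higher as a list (15, 0 and 17, camera 0.000497, adjusted p = 0.677 with an estimated correlation). Oxidative phosphorylation genes were called lower as a list (0, 12 and 15; 0.000121, adjusted p = 0.639 with an estimated correlation). Heat shock genes fell as a list (2, 9 and 5; 0.0279, adjusted p = 0.677 with an estimated correlation), as in the chaperone Hsph1 (−1.20), although the small chaperone Hspb1 rose by 2.35. Red blood cell genes fell (1, 4 and 2, camera 0.025, adjusted p = 0.474 with an estimated correlation), as in the heme enzyme Alas2 (−3.28) and the globin Hbb-bs (−3.002). Autophagy and lysosome genes were not called as a list (9, 6 and 9; 0.192), although progranulin, Grn, rose by 1.93 and the protease Ctsd by 1.43. FET family and ALS-linked genes were not called (2, 7 and 15; 0.395, median 0.006 and mean −0.053), with Fus higher and the tubulin Tuba4a lower (−0.95). Skeletal muscle genes were not called (test lower, 0.769), although their median was 1.55.

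**Figure D2:**
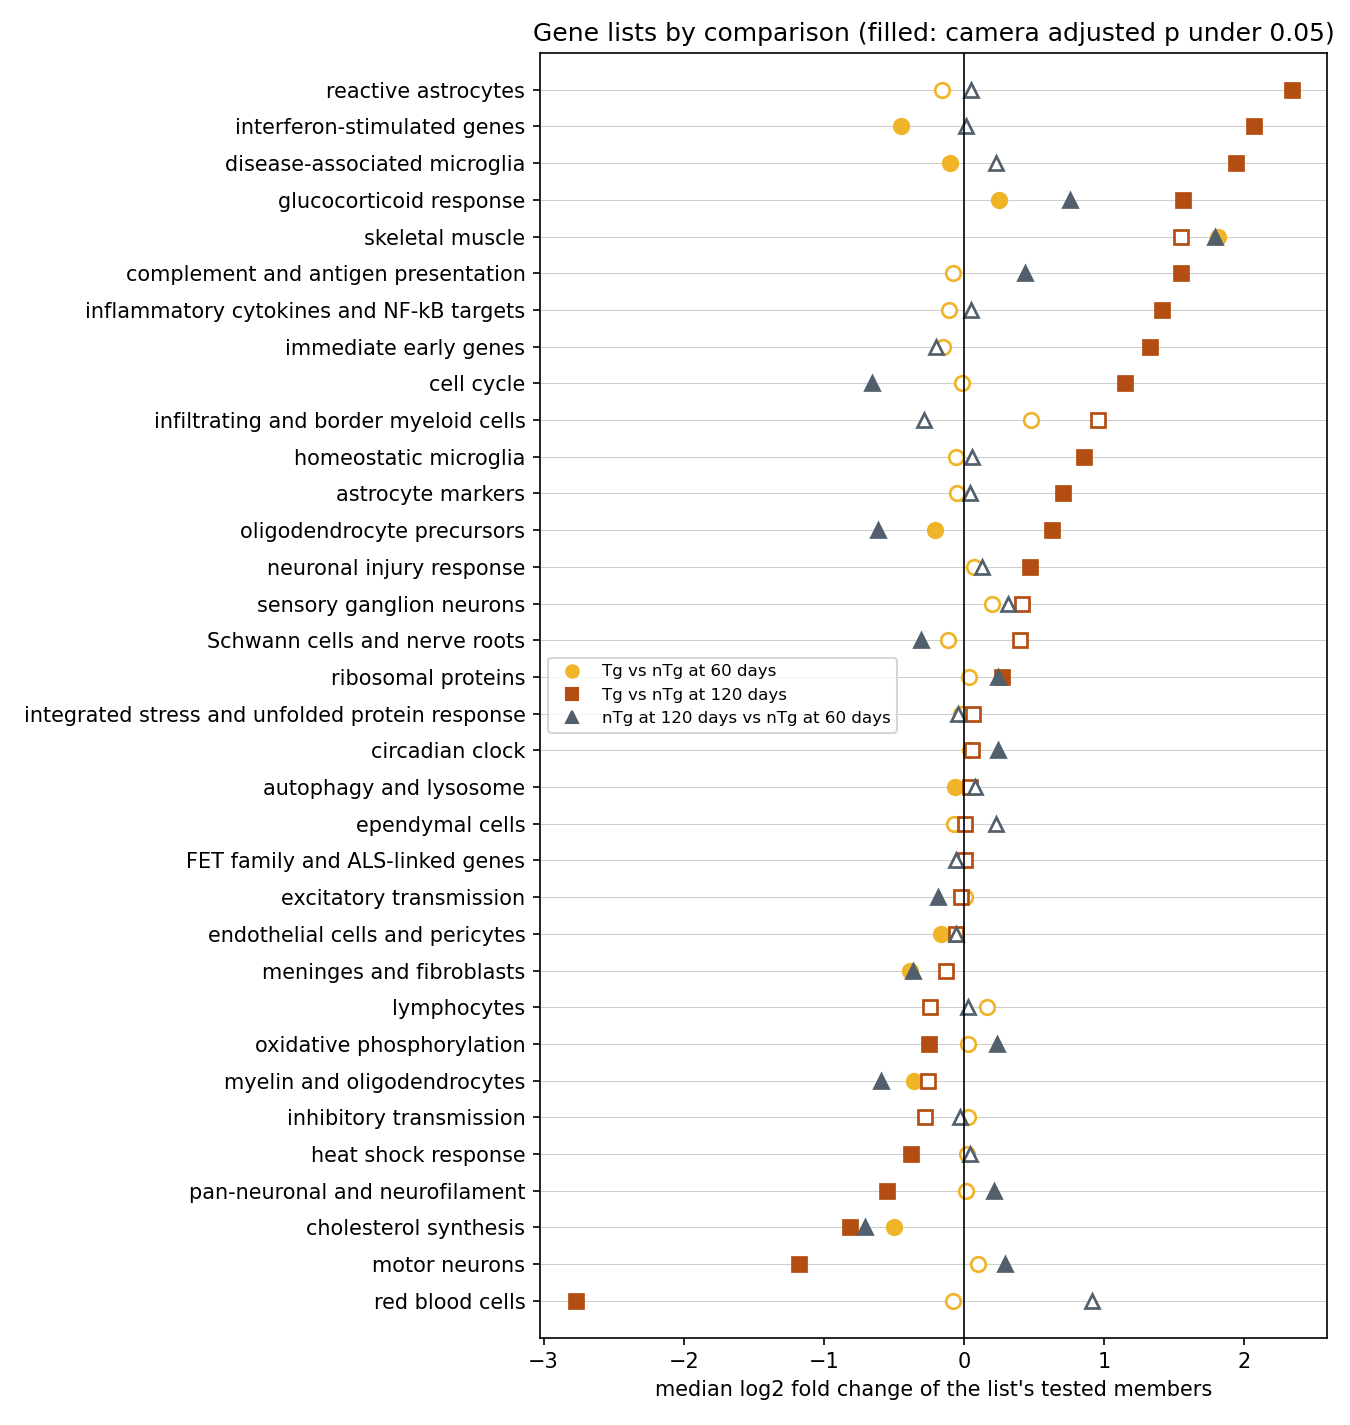
Median log2 fold change of each list for Tg against nTg at 60 days, Tg against nTg at 120 days and nTg at 120 against 60 days. Disease-associated microglia genes had medians of −0.10, 1.94 and 0.23, and cholesterol synthesis genes −0.50, −0.82 and −0.71.

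All Tg-120d and no nTg-120d file numbers were under 200, so a batch is not excluded. The count of 7479 was 3808 with the file-number term. No single library moved it beyond 6732 to 7886, and 136 of 142 named called genes kept their call without any library. Ended calls were those of heat shock genes (to 0.108 without nTg-120d replicate 5 or Tg-120d replicate 2 or 5), of red blood cell genes (0.0629 without Tg-120d replicate 5, 0.0691 with the share of reads without a feature as a covariate and 0.0506 without the libraries with a low share), of the citrullinating enzyme Padi4 (−4.69; 0.1 without nTg-120d replicate 5) and of Lum (19 fits, to 0.14), Actn3 (7, to 0.308), Gm42205 (6, to 0.0619), Bhlhe41 (5, to 0.0838) and Npas2 (5, to 0.0685). Calls were gained by myelin genes (0.0106 without Tg-120d replicate 2, 0.00347 with the file-number term), infiltrating myeloid genes (to 0.0225 without nTg-120d replicate 2 or Tg-120d replicate 4 or 5) and, without the libraries with a share of reads without a feature under 4%, inhibitory (0.028) and excitatory transmission (0.0473) and lysosome genes (0.0473, and 0.0401 with the covariate), and by integrated stress response genes (0.0379 without nTg-120d replicate 5).

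Tg against nTg log2 fold changes at 60 and 120 days had r = 0.0392 (Spearman −0.0354) over 14948 genes of at least 1 CPM. With 26 calls at 60 days, r cannot exclude weak early forms of later changes. Called in both were 13 genes (10.3 by chance), 11 of them with the same sign (5.4 by chance). No library was shared.

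The change from 60 to 120 days differed between Tg and nTg cord, with disease-associated microglia and reactive astrocyte genes more positive and motor neuron genes more negative in Tg as lists. The interaction and the comparison at 120 days share libraries and so differences in part. A wider age span in nTg is not excluded. Fus and Thy1 fell with age in Tg and were not called in nTg. Oligodendrocyte precursor genes were called as a list (adjusted p = 0.163 with an estimated correlation), and myelin genes were not (0.871). For this interaction 4686 genes were called, 2573 with a more positive and 2113 with a more negative change in Tg, 1534 of them at an absolute log2 value of at least 1 and 6776 genes at an unadjusted p below 0.05.

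The interaction of Fus was −0.50 ± 0.153 (adjusted p = 0.0172) and that of Thy1 −1.16 ± 0.189 (6.09e-05). Disease-associated microglia genes had 20 more positive, 0 more negative and 2 not passing (camera adjusted p = 5.42e-22), with Itgax at 4.78 ± 0.303, Cst7 at 6.02 and Clec7a at 5.11. Reactive astrocyte genes (16, 0 and 4, camera 1.11e-18) included Serpina3n at 3.16, and Gfap stood at 2.47 ± 0.204 (5.68e-09). Interferon-stimulated genes (23, 0 and 1; 7.06e-18, adjusted p = 0.0816 with an estimated correlation) included Cxcl10 at 5.28, and Mx1 stood at 6.50. Complement genes (18, 0 and 3; 6.18e-14) and inflammatory genes (19, 0 and 2, camera 1.73e-11) were more positive in Tg. So were homeostatic microglia genes (8, 0 and 6; 7.56e-06, adjusted p = 0.234 with an estimated correlation), astrocyte markers (10, 0 and 4; 1.46e-05, adjusted p = 0.0738 with an estimated correlation) and precursor genes (7, 0 and 5, camera 0.000227, adjusted p = 0.163 with an estimated correlation). Aif1 was at 1.39 ± 0.247 (0.000166) and Mbp did not pass (0.20, 0.542).

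Motor neuron genes were more negative with age in Tg than in nTg (1 more positive, 17 more negative, 1 not passing; 4.3e-11). Chodl was at −4.84 ± 0.224, Isl2 at −2.79 and Chat at −1.55 ± 0.204 (4.33e-06). Pan-neuronal genes (0, 15 and 4; 1.51e-09) included Nefh at −1.80 ± 0.166. Oxidative phosphorylation (0, 7 and 20; 0.000262, adjusted p = 0.688 with an estimated correlation) and cholesterol synthesis genes (0, 2 and 23, camera 0.00398, adjusted p = 0.72 with an estimated correlation) were more negative as well. Immediate early (11, 1 and 5; 0.000167, adjusted p = 0.306 with an estimated correlation) and glucocorticoid response genes (6, 0 and 9; 9.47e-05, adjusted p = 0.442 with an estimated correlation) were more positive, as were cell cycle genes (10, 0 and 9, camera 0.00158, adjusted p = 0.656 with an estimated correlation). Neuronal injury genes were more positive too (6, 0 and 11; 0.0186, adjusted p = 0.291 with an estimated correlation). Ribosomal protein genes (4 of 32; 0.0118, adjusted p = 0.783 with an estimated correlation) and lysosome genes (9, 1 and 14; 0.0169, adjusted p = 0.688 with an estimated correlation) were more positive. More negative were heat shock genes (2, 4 and 10, camera 0.0347, adjusted p = 0.688 with an estimated correlation), red blood cell genes (0, 5 and 2; 0.0347, adjusted p = 0.571 with an estimated correlation) and skeletal muscle genes (0, 1 and 12; 0.0483, adjusted p = 0.764 with an estimated correlation).

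The count of 4686 stayed within 4119 to 5087 without any single library, and 119 of 125 named called genes kept their call. Single libraries ended the list calls of cholesterol synthesis (0.0631 without nTg-60d replicate 4), lysosome (to 0.075 without nTg-120d replicate 4 or Tg-120d replicate 3), heat shock (5 fits, to 0.106), ribosomal proteins (4 fits, to 0.0753), red blood cells (4 fits, to 0.0753) and skeletal muscle (15 fits, to 0.161), and so did the file-number term for skeletal muscle (0.283), the covariate for heat shock (0.0516) and red blood cells (0.0739), the fit without the libraries with a low share for red blood cells (0.0706) and the fit without Tg-120d replicates 1 and 3 for lysosome genes (0.0576).

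From 60 to 90 days in Tg cord, ribosomal protein, oxidative phosphorylation, lysosome, disease-associated microglia and complement genes were called higher as lists. Excitatory transmission genes, with 8 of 18 members lower, were called lower as a list (each of these lists adjusted p = 0.571 with an estimated correlation). Motor neuron genes were not called as a list (0.637). The calls rested on few libraries. Between these ages 3652 genes were called, 1797 higher and 1855 lower, with 6891 at an unadjusted p below 0.05, and 548 had an absolute log2 fold change of at least 1, of which 35 rose and 513 fell.

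Ribosomal protein genes rose at 90 days (28 higher, 0 lower, 4 not passing, 31 higher adjusted over the list alone, camera adjusted p = 2.64e-14, adjusted p = 0.571 with an estimated correlation), as in Rpl5 (0.58) and Rpl13 (0.59), both of the large subunit. Oxidative phosphorylation genes rose (20, 0 and 7, camera 2.22e-09, adjusted p = 0.571 with an estimated correlation), such as the complex I gene Ndufb8 (0.61) and the cytochrome oxidase gene Cox5b (0.54). Autophagy and lysosome genes rose (13, 0 and 11; 7.56e-06, adjusted p = 0.571 with an estimated correlation), among them the autophagosome gene Gabarapl1 (0.51). Disease-associated microglia genes were called higher as a list (9, 0 and 13; 4.12e-05, adjusted p = 0.571 with an estimated correlation), as in the lipid receptor Trem2 (0.78). So were complement genes (7, 1 and 13, camera 0.000601, adjusted p = 0.571 with an estimated correlation), as in C1qa (0.71) and the invariant chain Cd74 (1.14). Aif1 rose by 0.63 ± 0.185 (0.0259) and Serpina3n by 0.46, while Gfap (0.19, 0.368), Mbp (0.12, 0.608) and Chat (−0.25, 0.243) did not pass. Ependymal (3, 0 and 10; 0.00608, adjusted p = 0.571 with an estimated correlation), immediate early (2, 0 and 15; 0.00608, adjusted p = 0.571 with an estimated correlation) and endothelial genes (5, 0 and 15, camera 0.0139, adjusted p = 0.571 with an estimated correlation) were called higher as lists. So were homeostatic microglia (4, 0 and 10; 0.0291, adjusted p = 0.658 with an estimated correlation), integrated stress response (5, 0 and 17; 0.0291, adjusted p = 0.615 with an estimated correlation) and astrocyte genes (2, 0 and 12, camera 0.0395, adjusted p = 0.571 with an estimated correlation), the stress list with the transcription factor Atf5 at 0.72.

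Excitatory transmission genes were called lower from 60 to 90 days as a list (1 higher, 8 lower, 9 not passing; 0.00076, adjusted p = 0.571 with an estimated correlation), with the metabotropic receptor Grm1 on chromosome 10 (10686059 to 11082356) at −0.65, the NMDA subunit Grin2b at −0.91 and the AMPA subunit Gria2 at −1.02. Oligodendrocyte precursor genes were called lower as a list (0, 4 and 8; 0.0291, adjusted p = 0.571 with an estimated correlation), such as the protocadherin Pcdh15 (−1.09) and the lineage factor Olig2 (−0.53), and inhibitory transmission genes were called lower as a list (2, 5 and 9; 0.0484, adjusted p = 0.615 with an estimated correlation). Fus did not pass (0.30 ± 0.114, 0.0602) and Thy1 rose by 0.45 ± 0.14 (0.0325). Larger single changes were those of Gm3608 (−5.48 ± 0.394, 1.02e-08), Padi4 (−4.30), the ribonuclease Rnaset2b (−3.89), Pxdn (−1.33), the slow troponin Tnnt1 (2.35) and the zinc transporter Slc39a7 (1.11).

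The count of 3652 was 2088 without a filter, 2 with the file-number term, 39 with an Xist covariate, 3 with the share of reads without a feature as a covariate and 3 without the libraries with a share under 4%. It was 4 and 12 without Tg-90d replicates 2 and 4 and 1236, 1682, 2055 and 2362 without Tg-60d replicates 1, 2, 3 and 4, and of 108 named called genes 105 lost their call without Tg-90d replicate 2 and 105 without Tg-90d replicate 4, with only Gm3608, Pxdn and Slc39a7 kept without any library. Lists that lost their call were endothelial genes (0.0575 without Tg-90d replicate 3), homeostatic microglia (to 0.0926 without Tg-90d replicate 1 or 2), stress response (4 fits, to 0.0567), astrocyte markers (5 fits, to 0.0784) and inhibitory transmission (16 fits, to 0.231), with the covariate homeostatic microglia (0.27), astrocyte markers (0.306), stress response (0.185), oxidative phosphorylation (0.0501) and ependymal genes (0.131), with the file-number term precursor (0.0867) and inhibitory transmission genes (0.123), without the libraries with a low share inhibitory transmission (0.0963) and stress response genes (0.0963), and without Tg-120d replicates 1 and 3 inhibitory transmission genes (0.0654).

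Tg-90d replicates 2 and 4 were also libraries with few reads outside genes. Their share of reads without a feature was 3.11% and 3.79%, against a mean of 3.95% in Tg at 90 days and 5.53% in Tg at 60 days, and their scores on the second principal component were 54.9 and 56.2. Other libraries with shares under 4% were nTg-120d replicates 2 (3.88%) and 3 (3.68%) and Tg-120d replicate 3 (3.78%), with second component scores of 38.0, 42.7 and 35.5. The first component carried 31.1% of the variance and set Tg at 120 days (mean 68.0) apart from all other groups (means −21.1 to −14.1).

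**Figure D3:**
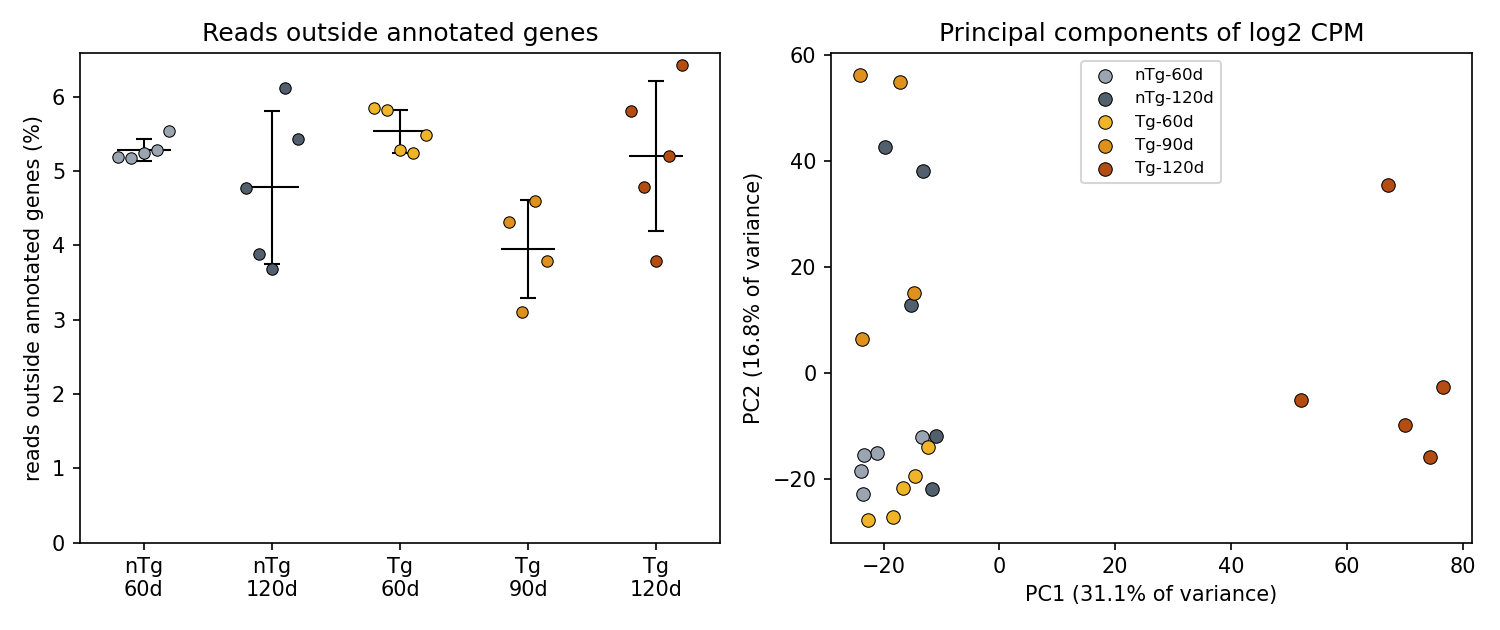
Share of reads without a feature in each library, and the first and second principal components, which carry 31.1% and 16.8% of the variance. The lowest share was 3.11% in Tg-90d replicate 2 and the highest 6.42% in Tg-120d replicate 5.

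Between 90 and 120 days disease-associated microglia, complement, inflammatory and reactive astrocyte genes rose as lists in Tg cord. Other lists were called with a call lost under an estimated correlation, namely motor neuron (lower, adjusted p = 0.0706 with an estimated correlation), pan-neuronal (lower, 0.0706), myelin (lower, 0.54), cholesterol synthesis (lower, 0.281), oxidative phosphorylation (lower, 0.507) and interferon-stimulated genes (higher, 0.141). Fus, Thy1, Gm10167 and Gm7199 fell between the same ages. Between these ages 7994 genes were called, 4295 higher and 3699 lower, 2001 of them with an absolute log2 fold change of at least 1, and 9501 had an unadjusted p below 0.05.

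Fus fell by −0.74 ± 0.114 (adjusted p = 1.38e-05) and Thy1 by −1.28 ± 0.141 (1.49e-07) from 90 to 120 days, with Gm7199 at −1.88 ± 0.25 and Gm10167 at −1.78 ± 0.193. Motor neuron genes fell as a list (2 higher, 15 lower, 2 not passing, camera adjusted p = 5.17e-08, adjusted p = 0.0706 with an estimated correlation), with Chodl at −4.72, Isl2 at −2.15 and Chat at −1.02 ± 0.153 (1.12e-05), while the neuropeptide Uts2 rose by 2.43. Pan-neuronal genes fell (2, 15 and 2, camera 2.26e-08, adjusted p = 0.0706 with an estimated correlation), with Nefh at −1.94. Myelin genes fell (2, 12 and 7; 0.000856, adjusted p = 0.54 with an estimated correlation), among them Gjc2 (−1.90), the sulfatide enzyme Gal3st1 (−1.27), the hydroxylase Fa2h (−1.08) and Mbp (−0.50, 0.0158). Cholesterol synthesis genes fell (0, 23 and 2; 2.18e-11, adjusted p = 0.281 with an estimated correlation), with the decarboxylase Mvd at −1.95 and Dhcr24 at −1.66. Oxidative phosphorylation genes fell (0, 21 and 6, camera 3.52e-07, adjusted p = 0.507 with an estimated correlation). Heat shock genes were called lower as a list (2, 8 and 6; 0.0208, adjusted p = 0.589 with an estimated correlation) and red blood cell genes fell (0, 4 and 3; 0.00287, adjusted p = 0.325 with an estimated correlation), with the globin Hbb-bt at −3.46.

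Disease-associated microglia genes rose from 90 to 120 days (19, 0 and 3, camera 2.37e-15), with Gpnmb at 4.74 and Itgax at 4.57, and homeostatic genes rose (11, 1 and 2; 0.000544, adjusted p = 0.414 with an estimated correlation). All 24 interferon-stimulated genes rose (2.65e-15, adjusted p = 0.141 with an estimated correlation). Complement (17, 1 and 3; 4.03e-11), inflammatory (20, 0 and 1, camera 4.32e-10), reactive astrocyte (19, 0 and 1; 1.87e-15) and astrocyte marker genes (10, 2 and 2; 0.000939, adjusted p = 0.201 with an estimated correlation) rose. Serpina3n stood at 3.14, Gfap at 2.04 ± 0.161 (7.92e-10) and Aif1 at 1.06 ± 0.185 (6.87e-05). Precursor genes were called higher as a list (6, 1 and 5, camera 0.0437, adjusted p = 0.507 with an estimated correlation), and 3 fits without a single library (to 0.114) and the file-number term (0.154) ended that call. Glucocorticoid response genes rose (14, 0 and 1; 1.52e-09, adjusted p = 0.19 with an estimated correlation), such as Mt1 (2.80), the sulfotransferase Sult1a1 (3.22) and Fkbp5 (2.44). Neuronal injury genes were not called as a list (8, 1 and 8; 0.121, but 0.049 without Tg-120d replicate 5), although Atf3 rose by 3.00 and the regeneration-associated Sprr1a by 3.98. Large single rises included Plin4, a lipid droplet coat protein on chromosome 17 (56100591 to 56109803) (6.19 ± 1.00), Cd22 (5.79) and Gm3608 (5.19). Hoxc10 stood at 6.35 through Tg-120d replicates 1 and 3 and at −0.592 without them (0.624). Large falls were those of the protocadherin Pcdh12 (−3.64), the vascular gene Gkn3 (−3.57) and the glaucoma gene Myoc (−3.37).

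All Tg-120d and no Tg-90d file numbers were under 200, so a batch is not excluded. The count of 7994 was 4111 with the file-number term and 4650 with an Xist covariate. It ran from 6608 to 8406 without any single library, and 134 of 147 named called genes kept their call. Calls ended for the vesicular glutamate transporter Slc17a7 (2.15; 0.0539 without Tg-120d replicate 3), the ribosomal gene Rpl13a (−0.45; 0.105 without Tg-90d replicate 4), the mitotic gene Prc1 (1.49; 0.0514 without Tg-120d replicate 2) and the muscle myosin Myh1 (3.92; 0.0985 without Tg-120d replicate 2).

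Among the Tg animals at 120 days, replicates 1 and 3 held more transcripts of caudal Hox genes, the body-axis transcription factors, than the others. Hoxc10 on chromosome 15 (102966796 to 102971893) was at 43.99 and 50.69 CPM in them and at 0 to 0.771 CPM in every other library. Hoxc5, a cervical Hox gene chosen after its values were seen, was at 3.40 and 3.35 CPM in them against 12.1 to 21.4 CPM in the other Tg animals at 120 days and 21.6 to 36.7 CPM elsewhere. Against the other Tg-120d libraries, the 6 genes of paralog groups 9 and 10 were higher in both (median log2 differences 2.86 and 3.22, least for Hoxb9 at 0.511 and 0.901), and 9 of 10 genes of groups 4 to 6 were lower in each (medians −0.38 and −0.573). Without both libraries 6730 genes were called for Tg against nTg at 120 days, 6054 of them shared, and the log2 fold change of Hoxc10 was −1.04 instead of 5.88.

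**Figure D4:**
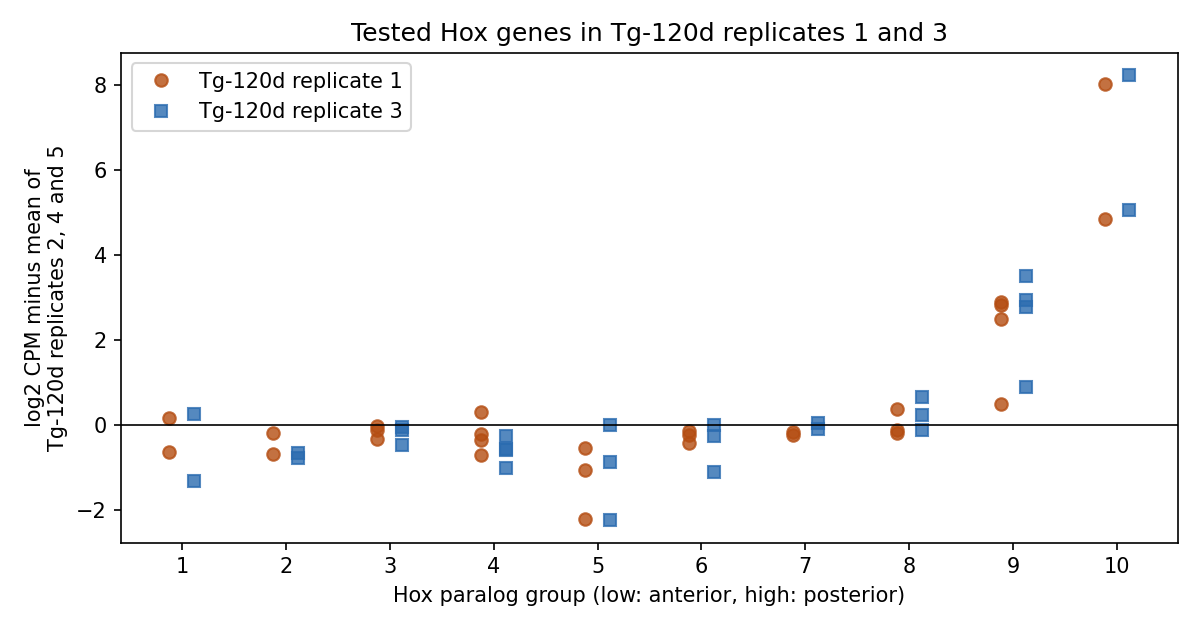
Log2 CPM of tested Hox genes by paralog group in Tg-120d replicates 1 and 3, minus the mean of the other Tg-120d libraries. Hoxc10 was at 43.99 and 50.69 CPM in Tg-120d replicates 1 and 3 and at most 0.771 CPM in any other library.

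Over the whole span from 60 to 120 days in Tg cord, disease-associated microglia, complement, inflammatory and reactive astrocyte genes rose as lists. Ribosomal protein and lysosome genes were called higher and excitatory transmission genes lower as lists (each adjusted p = 0.415 with an estimated correlation), the last of these not without Tg-120d replicate 4 (0.0546). Motor neuron (adjusted p = 0.0728 with an estimated correlation) and pan-neuronal genes (0.0733) were called lower. Oxidative phosphorylation genes were not called over the whole span (0.411). In this span 7016 genes were called, 3797 higher and 3219 lower, 1771 of them with an absolute log2 fold change of at least 1, and 8528 had an unadjusted p below 0.05.

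Fus fell by −0.44 ± 0.108 (adjusted p = 0.00216) and Thy1 by −0.83 ± 0.134 (2.47e-05) from 60 to 120 days. Disease-associated microglia (19, 0 and 3, camera adjusted p = 8.15e-21), complement (19, 0 and 2, camera 1.89e-17), inflammatory (20, 0 and 1; 6.61e-13) and reactive astrocyte genes (18, 0 and 2; 1.17e-18) rose. Itgax and Gpnmb both reached 5.03, Cst7 6.01 and Serpina3n 3.60, with Gfap at 2.24 ± 0.149 (2.71e-11) and Aif1 at 1.69 ± 0.177 (4.81e-08). All 24 interferon-stimulated genes rose (1.74e-18, adjusted p = 0.0743 with an estimated correlation). So did astrocyte markers (11, 1 and 2, camera 2.09e-06, adjusted p = 0.0666 with an estimated correlation) and homeostatic microglia genes (11, 0 and 3; 2.23e-06, adjusted p = 0.187 with an estimated correlation). Ribosomal protein genes rose (30, 0 and 2; 5.99e-09, adjusted p = 0.415 with an estimated correlation), as in Rpl5 (0.55). Lysosome genes were called higher as a list (11, 1 and 12, camera 0.00031, adjusted p = 0.415 with an estimated correlation), as in Grn (2.20). Glucocorticoid response (12, 0 and 3; 1.02e-08, adjusted p = 0.187 with an estimated correlation), immediate early (12, 2 and 3; 0.000562, adjusted p = 0.373 with an estimated correlation) and neuronal injury genes (8, 0 and 9, camera 0.00235, adjusted p = 0.144 with an estimated correlation) were called higher as lists. Mt1 was at 3.06, Atf3 at 3.52 and Sprr1a at 4.86.

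Motor neuron genes fell over the span (2 higher, 16 lower, 1 not passing; 5.98e-08, adjusted p = 0.0728 with an estimated correlation), with Chodl at −4.55 and Chat at −1.26 ± 0.147 (2.4e-07). Pan-neuronal (0, 15 and 4; 5.98e-08, adjusted p = 0.0733 with an estimated correlation), excitatory transmission (1, 8 and 9; 0.0198, adjusted p = 0.415 with an estimated correlation) and myelin genes (1, 12 and 8, camera 0.000467, adjusted p = 0.43 with an estimated correlation) were called lower as lists. Nefh was at −1.59, the AMPA subunit Gria4 at −0.60 and Fa2h at −1.27, while Mbp did not pass (−0.37, 0.0583). Cholesterol synthesis genes fell (0, 24 and 1; 1.64e-11, adjusted p = 0.236 with an estimated correlation), with Dhcr24 at −1.55. Heat shock (2, 8 and 6; 0.0412, adjusted p = 0.582 with an estimated correlation) and red blood cell genes (0, 5 and 2, camera 0.0285, adjusted p = 0.415 with an estimated correlation) were called lower as lists too. Oxidative phosphorylation genes were not called as a list (0, 3 and 24; 0.411, median −0.04, but 0.0493 without Tg-120d replicate 3), nor were skeletal muscle genes (1, 0 and 12; test lower, 0.742, median 1.70 and mean 1.33).

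The count of 7016 ran from 6104 to 7393 without any single library, and 136 of 148 named called genes kept their call, with the red cell anion exchanger Slc4a1 (−2.49; 0.258) and the collagen Col2a1 (−2.43; 0.809) lost without Tg-60d replicate 3. Among lists, excitatory transmission (0.0546 without Tg-120d replicate 4), red blood cells (0.083 without Tg-120d replicate 5) and heat shock (7 fits, to 0.108) lost their call.

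In nTg cord at the later age myelin, cholesterol synthesis (each adjusted p = 0.413 with an estimated correlation), oligodendrocyte precursor (0.0672) and cell cycle genes (0.499) were called lower as lists. Complement genes (2 of 21 members higher, adjusted p = 0.413 with an estimated correlation), glucocorticoid response genes (2 of 15, 0.499), clock genes (2 of 15, 0.471) and motor neuron genes (0 of 19, 0.413) were called higher as lists. Between nTg at 60 and 120 days 827 genes were called, 360 higher and 467 lower, 128 of them with an absolute log2 fold change of at least 1, and 4523 had an unadjusted p below 0.05.

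Myelin genes were called lower with age in nTg as a list (0 higher, 10 lower, 11 not passing, 16 lower adjusted over the list alone, camera adjusted p = 2.98e-12, adjusted p = 0.413 with an estimated correlation). The raft protein Mal on chromosome 2 (127633226 to 127656695) was at −1.16 ± 0.208 (0.00719), the main myelin protein Plp1 at −1.17, the tetraspanin Tspan2 at −1.09 and Mbp at −0.58 (0.0364). Oligodendrocyte precursor genes were called lower as a list (0, 6 and 6, 9 lower adjusted over the list alone; 8.06e-10, adjusted p = 0.0672 with an estimated correlation). Gpr17, a receptor of differentiating precursors on chromosome 18 (31942997 to 31949636), was at −2.37 ± 0.462, with the lineage factors Sox6 (−0.85) and Olig2 (−0.64) and the proteoglycan Cspg4 (−0.42). Cholesterol synthesis genes were called lower as a list (0, 12 and 13, 19 lower adjusted over the list alone; 2.68e-13, adjusted p = 0.413 with an estimated correlation), with the rate-limiting reductase Hmgcr on chromosome 13 (96648967 to 96670936) at −1.22, the cyclase Lss at −1.31 and the synthase Hmgcs1 at −1.37. Cell cycle genes were called lower as a list (0, 2 and 17, 9 lower adjusted over the list alone; 6.86e-06, adjusted p = 0.499 with an estimated correlation), as in Top2a (−2.21) and the mitotic kinase Aurkb (−1.86). Meninges and fibroblast genes were called lower as a list (0, 1 and 15; 0.00182, adjusted p = 0.638 with an estimated correlation), with the collagen Col3a1 at −1.96. Schwann cell (0 of 11 called; 0.031, adjusted p = 0.618 with an estimated correlation) and excitatory transmission genes (0 of 18; 0.00382, adjusted p = 0.499 with an estimated correlation) were lower as lists. Among single genes, Glra4 fell by −2.75 ± 0.357 (0.00107), elastin, Eln, by −1.94 and the fibrillin Fbn2 by −1.82.

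Complement genes were called higher with age in nTg as a list (2, 0 and 19, 8 higher adjusted over the list alone; 6.89e-05, adjusted p = 0.413 with an estimated correlation), as in the central component C3 (0.69) and C1qa (0.56). Glucocorticoid response genes were called higher as a list (2, 0 and 13, 7 adjusted over the list alone; 8.33e-05, adjusted p = 0.499 with an estimated correlation), as in Mt2 (1.01) and Mt1 (0.76). Clock genes were called higher as a list (2, 0 and 13, camera 0.0285, adjusted p = 0.471 with an estimated correlation). Higher as lists with few or no members called were oxidative phosphorylation (1 of 27, 3.12e-08) and ribosomal protein genes (0 of 32, 6.92e-08). So were motor neuron (0 of 19, 0.000155), pan-neuronal (1 of 19, 0.0137) and skeletal muscle genes (0 of 13, 0.00171). With an estimated correlation these last lists had adjusted p = 0.499, 0.594, 0.413, 0.57 and 0.638 in this order. Sprr1a rose by 4.15, the ceramidase Acer2 by 1.38 and Serpina3n by 0.45, and Jun fell by −0.52. Fus (0.06, 0.769), Thy1 (0.33, 0.137), Chat (0.28, 0.223), Gfap (−0.24, 0.314) and Aif1 (0.30, 0.29) did not pass.

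The count of 827 was 404 without a filter, 1082 (612 higher, 470 lower) with a filter at a mean of 1 CPM, 1594 with DESeq2, 364 with only the groups compared, 2 with the file-number term and 1.8e2 without the libraries with a share of reads without a feature under 4%. It was 170, 235, 215, 1911 and 116 without nTg-60d replicates 1, 2, 3, 4 and 5 and 379, 272, 1.8e2 and 1396 without nTg-120d replicates 1, 2, 3 and 5, and 43 of 58 named called genes lost their call in some fit, such as Hmgcs1, Plp1 and Tspan2 without nTg-60d replicate 5 (each 0.0575) and Mbp in 6 fits (to 0.125). Mal, Gpr17, Sox6, Olig2, Lss, Hmgcr, Glra4, Eln, Fbn2, Acer2, Sprr1a and Jun kept theirs, while the lists of meninges (0.118 without nTg-120d replicate 1), pan-neuronal genes (0.0528 without nTg-120d replicate 5), clock genes (0.0658 without nTg-120d replicate 5) and Schwann cells (5 fits, to 0.118) did not, nor did clock genes (0.0852) and Schwann cells (0.266) with the file-number term and excitatory transmission genes without the libraries with a low share (0.219).

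The log2 fold changes of age in nTg and of the step from 60 to 90 days in Tg, comparisons that share no library, correlated at r = 0.404 (Spearman 0.556) over 14948 genes. Both later groups hold libraries with a share of reads without a feature under 4% (nTg-120d replicates 2 and 3, Tg-90d replicates 2 and 4), and the correlation was −0.0464 (Spearman 0.0753) without these libraries and Tg-120d replicate 3, and 0.172 (0.295) with that share as a covariate. With all libraries 201 genes were called in both with the same sign (80.5 by chance) and 4 with opposite signs (161 in both by chance). Pxdn and the mitotic kinesin Kif14 (−1.33 and −1.25 in Tg) were among the genes called in both. Of the 3652 genes called from 60 to 90 days in Tg, 88.7% had the same sign in nTg with age (66.6% in the fit without the libraries with a low share), and 24 were called with the same sign against the mean of nTg.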

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

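The tests of the caudal Hox pattern, of age shared with nTg animals and of a smaller neuronal share were chosen after the results were seen. Those with the share of reads outside genes as a covariate and without the libraries with caudal Hox transcripts were chosen after the data were seen, with their limits set before their results, and the other tests were written before.

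Single libraries stood apart from the rest of their group by Dixon's gap test in 20 of 210 groups of values, where chance gives about 1 in 20, or 10.5. In Tg-60d these were replicate 4 for Chat (5.58 log2 CPM, next 5.22), motor neuron genes (4.54, next 4.31) and glucocorticoid response genes (5.92, next 5.16), replicate 1 for complement genes (3.35, next 3.71), replicate 5 for myelin (8.49, next 8.91) and clock genes (5.2, next 5.07), and replicate 3 for cell cycle genes (1.23, next 0.557). In nTg-60d they were replicate 4 for clock (5.17, next 4.98) and infiltrating myeloid genes (1.26, next 0.687), replicate 3 for heat shock genes (6.97, next 6.58) and replicate 5 for the share of reads outside genes (5.54%, next 5.28%). In nTg-120d, replicate 5 stood apart for Fus (6.66, next 7.22), immediate early genes (2.87, next 2.62) and heat shock genes (7.27, next 6.55). In Tg-90d, replicate 2 stood apart for skeletal muscle genes (2.78, next −0.0131) and replicate 4 for inhibitory transmission genes (5.82, next 6.41). In Tg-120d, replicate 3 stood apart for pan-neuronal (8.81, next 8.49) and immediate early genes (4.65, next 3.65), replicate 2 for glucocorticoid response genes (6.2, next 7.34) and replicate 5 for its total (25.3 M, next 30.6 M).

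The difference between Tg and nTg changed from 60 to 120 days in 4686 genes by a test of the interaction. It did so for Fus (−0.502, adjusted p = 0.0172), Thy1 (−1.159, 6.09e-05), Chat (−1.547, 4.33e-06), Gfap (2.472, 5.68e-09) and Aif1 (1.389, 0.000166). Hoxd10, a caudal Hox gene left out by the expression filter, reached 6.96 CPM in a Tg-120d library (next 5.67), against at most 0.0292 CPM in nTg.

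Caudal Hox transcripts were higher in Tg-120d replicates 1 and 3 than in the other Tg-120d libraries, from 0.511 and 0.901 for Hoxb9 to 8.02 and 8.22 for Hoxc10 (log2 differences). A more caudal piece of spinal cord fits, since genes of groups 4 to 6 were lower in both (medians −0.38 and −0.573) while groups 9 and 10 were higher (2.86 and 3.22). Hox genes switched on through the transgene in these animals and a label exchanged with a sample of another cord level were not tested and stay open.

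The 3652 genes called between Tg at 90 and 60 days rested on Tg-90d replicates 2 and 4. A gradient of RNA composition marked by the share of reads outside genes fits: with that share as a covariate, 38% of the median signed log2 fold change was kept (0.474 without and 0.18 with it, median standard errors 0.134 and 0.126). With a term for a library batch read from the file numbers, 88.3% was kept (86% to 91.4% without single 60-day libraries). By the limit set beforehand this goes against a batch as the cause of the fold changes. But the term could be estimated only within the 60-day groups, where 2 nTg-60d libraries and 1 Tg-60d library had file numbers from 200. All 4 Tg-90d libraries had such numbers, so a batch is not excluded. The calls fell to 2 with the term, with a median signed log2 fold change of 0.419 and a median standard error of 0.178 (0.474 and 0.134 without it). Why they ended was not tested. Age shared with nTg animals cannot be told apart from this gradient. In nTg 88.7% of the genes had the same sign, but nTg-120d replicates 2 and 3 also had a low share of reads outside genes. It was 79.4% with the covariate and 66.6% without the libraries with a low share, where the median signed log2 fold change in nTg went from 0.217 to 0.064. A change through the transgene at 90 days stays open, since no nTg group of that age exists.

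Fus and Thy1 counts were lower in Tg at 120 than at 90 days. A smaller share of neuronal RNA was argued against as the whole cause, since pan-neuronal genes without Thy1 had a median of −0.611 (14 of 18 called lower) against −1.877 ± 0.25 for Gm7199, which is nearly silent in nTg. The test was first set against Fus (−0.74), which gave no decision because Fus also counts mouse transcripts. Scaling of the libraries was argued against (the smallest fall of Fus under other scalings was −0.733), and so were the Tg-120d libraries with caudal Hox transcripts (−0.7917 without them, against −0.7449). A loss of the neurons with most transgene transcripts stays open: motor neuron genes had a median of −1.02, with 3 of 19 at or below Gm7199, and lower transgene activity stays open as untested.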

How the results depend on the processing

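The tests without Tg-120d replicates 1 and 3, without libraries of a no-feature share under 4%, and with that share as a covariate were chosen after the data were seen. Of 12572 alternative values for 790 named genes, 11252 kept their call and direction, 1307 were weaker, 10 stronger and 3 reversed, and of 2448 for 272 list tests 2151 were the same, 210 weaker, 86 stronger and 1 reversed. Without single libraries the called genes ran from 12 to 289 (Tg against nTg at 60 days), 6732 to 7886 (120 days), 4 to 4806 (Tg at 90 against 60 days), 6608 to 8406 (120 against 90), 6104 to 7393 (120 against 60), 116 to 1911 (nTg), 10 to 1732 (90 days against the mean of nTg) and 4119 to 5087 (interaction), called lists from 118 to 126 and called named genes from 636 to 763 (769 with all libraries). Where counts moved below, the cause was not tested unless given.

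For Tg against nTg at 60 days the 26 called genes became 9 with a filter at a mean of 1 CPM, 74 with DESeq2, 47 with voom, 15 with the file-number term and 15 with thinned counts. At 120 days 7479 became 3808 with the file-number term and 1695 with a fold limit of 1 on the log2 scale. For Tg at 90 against 60 days 3652 became 2088 without a filter, 2 with the file-number term, 39 with the Xist covariate, 3 with the no-feature covariate, 3 without libraries of a low no-feature share and 548 with the fold limit. Scaling by library total only called 3282 genes there, 1179 higher and 2103 lower (35.9% higher, against 49.2%), and a filter at 1 CPM gave 60.4% higher. For 120 against 90 days 7994 became 4111 with the file-number term, 4650 with Xist and 2001 with the fold limit, and for 120 against 60 days 7016 became 1771 with the fold limit. In nTg 827 (43.5% higher) became 404 (31.2%) without a filter, 1082 (56.6%) with a filter at 1 CPM, 1594 with DESeq2, 364 (30.2%) with only the groups compared, 2 with the file-number term, 1.8e2 without low no-feature libraries and 128 with the fold limit. For Tg at 90 days against the mean of nTg 33 became 1272 with DESeq2, 52 with voom, 16 with only the groups compared, 22 with library totals, 19 with the file-number term, 13 with Xist, 18 with the no-feature covariate, 9 without low no-feature libraries, 17 with the fold limit, 3332 against nTg at 60 days alone and 12 against nTg at 120 days alone. The interaction went from 4686 to 1534 with the fold limit. Of 124 called lists, fry ended the calls of 43 and called 13 others (94 in all), 19 were called with an estimated correlation, and the file-number term left 506 of the named genes called.

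The 2 left-out Tg-120d libraries held the caudal Hox transcripts, and without them Hoxc10 reversed at 120 days against nTg (−1.043), against 90 days (−0.592) and against 60 days (−0.4521). Skeletal muscle genes at 90 days, not called against the mean of nTg (test higher, 0.758), were called lower with the no-feature covariate (1.95e-07), and the cause was not tested. Other counts without these libraries were 36, 6730, 4203, 7601, 5899, 1068, 39 and 4326 in the order above. Replicate numbers do not pair the libraries: of 46 pairs with the same number 11 correlated above 0.1 (−0.375 to 0.341, median 0.0185), and in 10 of these pairs the first library correlated best with its own number in the other group. With the replicate block 48 genes were called for Tg against nTg at 60 days, 2216 for Tg at 90 against 60 days and 17 for Tg at 90 days against the mean of nTg.

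Chance was judged for each count by the share of 100 splits of the same libraries that called as many genes. A count reached only by the real grouping argues against chance. Only the real grouping (1 of 100) gave as many genes for Tg against nTg at 60 days (26, highest other 16) and 120 days (7479, 2631), Tg at 90 against 60 days (3652, 1), 120 against 90 days (7994, 6861) and 120 against 60 days (7016, 2393) and the interaction (4686, 4418). The highest other splits of the interaction (4418 and 3758) kept the real groups at 120 days and regrouped only the libraries at 60 days. They hold the difference at 120 days, and no split that mixed the groups at 120 days called more than 77. The splits of the interaction therefore cannot tell a changed difference from a difference at 120 days alone. For nTg 3 of 100 did (827, highest other 1795), and for 90 days against the mean of nTg 3 of 100 (33, highest other 5047). In these comparisons some other splits called more genes than the real grouping, so chance is not excluded for their counts. The split with 5047 put nTg-120d replicates 1, 2 and 3 with Tg-90d replicate 4, and points to a structure of the samples rather than of the groups. The nTg split with 1795 put nTg-60d replicate 4 with nTg-120d libraries and points to a structure of the samples too. File numbers under 200 were those of 3 of 5 nTg-60d, 4 of 5 Tg-60d and all Tg-120d libraries, so the file-number term was nearly set by the groups.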

Other observations

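All genes here were chosen after their values were seen, and none of the values was tested further. Nes, a filament of progenitors and reactive astrocytes, stood at 24.6 and 17.0 CPM in nTg at 60 and 120 days and at 16.2, 25.7 and 54.3 CPM in Tg at 60, 90 and 120 days. Plin4, a lipid droplet coat protein, went from 2.75 CPM in Tg at 90 days to 201 ± 83.4 CPM in Tg at 120 days, with 32.6 ± 37.6 CPM in nTg at 120 days. The interferon-induced genes Mx1 (1.29 to 14.4 CPM) and Ifit3 (10.2 to 58.6 CPM) spread widely among the Tg animals at 120 days. The globin gene Hbb-bs was at 37.6 CPM in Tg at 120 days and at group means of 149 to 315 CPM elsewhere.

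Among nTg-60d libraries, replicate 4 had the lowest list mean of cholesterol synthesis genes (5.55 log2 CPM, against 6.30 to 6.90 in the others). The sterol enzyme Hmgcs1 was at 266 CPM in it and at 656 to 1190 CPM in the others, the glycine receptor gene Glra4 was at 0.730 against 4.04 to 6.91 CPM, and the calcium-sensing receptor gene Casr at 0.0876 against 0.656 to 2.17 CPM. The labels give this group an age of 30 to 60 days.

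The muscle actin gene Acta1 was at 26.7 CPM in Tg-90d replicate 2 and at 59.1 and 56.2 CPM in Tg-120d replicates 2 and 3. Tg-60d replicate 3 had the proliferation gene Mki67 at 10.98 CPM and the neutrophil gene S100a8 at 40.6 CPM. The pseudogene Gm3608 was at 0.150 CPM in Tg at 90 days and at group means of 5.35 to 6.81 CPM elsewhere.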
